A study of Mus musculus with 4 samples.

How the data were processed

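RNA of MEFs of 2 genotypes, untreated or TNF-treated, was measured on 4 Affymetrix whole-genome mouse arrays, 1 per condition. The deposited values are log2 probe set values, as judged from their range of 2.79 to 14.40 and medians of 6.21 to 6.3. Per the submitters' processing notes, MAS5 was used, with no version given. The nearly equal quantiles of the 4 arrays and the tight lower bound are not those of plain MAS5 signals, so the summary method, the normalization between arrays and any filter stay unknown, and with them how far the authors' processing compressed low values or differences. The labels' description texts speak of embryo stages that have nothing to do with fibroblasts and were not used. Groups follow the titles and source names, which disagree with the genotype entry for 2 of the 4 samples. The labels do not say whether the 2 arrays of a genotype come from separate cell preparations, so p-values speak of these arrays only. With no replicates, their error is how far the TNF response differs between the genotypes, moderated across genes.

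Of the 45101 probe sets, 64 are controls, 34945 name 1 gene, 932 name several and 9160 are unnamed here. For 34741 named probe sets the Entrez identifier matched the reference gene table (assembly GRCm38.p6, used for names and gene order only, since the files name no build), and 0 symbols changed. This gives 18193 genes. Values were returned to the linear scale, where the trimmed means (2% trimmed) of the arrays differed by 2.94%, under the 5% set for rescaling, so they were used as deposited. Signals under the 50th percentile of all values (77.0, log2 6.27) were raised to this floor, and 12225 genes lay above it on at least 1 array. Each gene is represented by its probe set of highest mean. A gene counts as 2-fold higher or lower at a log2 difference of at least 1, and a value at the floor on one side makes the fold a bound. For genes with a second probe set, the second had the same sign for 98.6% of the 144 genes at least 2-fold apart by the first in wild-type TNF response, 98.9% in knockout cells, 93.6% for the difference of responses, and 96.6% and 96.8% for the genotype differences. In that order, the second was itself at least 2-fold apart the same way for only 93 of 144, 63 of 93, 25 of 47, 100 of 145 and 104 of 155 genes.

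The comparisons were the TNF response in each genotype, the difference of the responses, and the genotype difference in each treatment, all of 1 array against 1 and without p-values. An additive limma model of genotype and TNF was fitted to 11817 genes above the floor on at least 2 arrays (lmFit and eBayes with an intensity trend, 1 residual degree of freedom, prior degrees of freedom 3.52, Benjamini-Hochberg). Gene lists were compared by median with 10000 random lists matched on mean expression, and in limma with camera (preset correlation 0.01, and estimated) and fry. The lists were NF-kB pathway, chemokines, cytokines, leukocyte adhesion, interferon-stimulated, antigen presentation, complement and acute phase, proteases, redox and prostaglandin, matrix, contractile, cell cycle, cell death, p53 targets, sphingolipid metabolism, FAN and BEACH family, cholesterol synthesis, housekeeping, Nsmaf neighbours, Hox, sex-linked, and markers of 9 cell types. Some list members are not analysed here. The p53 target list as fixed also holds Cdkn2a and Cdkn2b, which are not themselves p53 targets. Named genes are Nsmaf, a fixed set of TNF targets, the 6 highest and 6 lowest genes whose other probe sets go the same way and the 3 largest bounds of each comparison, up to 4 members per list at least 2-fold apart, and the 6 largest limma changes each way. Further list members past the limma test were named after their values were seen. The groups, lists, rules and alternatives were fixed before the data were examined, on the assumption of linear signals; the values proved to be log2 as deposited, and were returned to the linear scale as described.

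The limma step was tested on simulated data for the TNF effect, with 200 changed genes. The first version gave every gene its own fitted posterior variance: 98.0% of 2-fold changes were recovered, with 91 false calls and 66 genotype calls where none was simulated, and 94.5% of 4-fold changes with 20 false calls and 0 genotype calls. Because of these false calls the simulation, and not the limma test, was then changed to draw variances from the fitted prior. It then recovered 0 of 200 at 2-fold with 0 false calls, and 90.5% at 4-fold with 9 false calls. How many of the limma calls are false, and how often 2-fold changes are found, therefore depends on a variance distribution that 4 arrays cannot settle. The limma counts are to be read with that limit. The simulation also held no genotype effect, unlike the data. There the fit did call changes under 2-fold, such as Trp53inp1 between genotypes (0.78 log2).

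Alternatives were other floors (30th and 70th percentile, or none with log2(value + 16)), quantile normalization, centring, the mean of all probe sets, probe sets with no cross-hybridising suffix, thresholds of 1.5-fold and 3-fold, other limma variance models and filters, and no genotype term. The spread used to judge whether a value moved (between probe sets of a gene, between random lists, or of a bootstrap) was chosen after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.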

Results

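Expression was measured in mouse embryonic fibroblasts (MEFs), primary cells grown out of embryos, of C57BL/6 background that were wild type or lacked FAN. FAN, encoded by Nsmaf, is an adaptor protein that binds the TNF receptor and is linked to the activation of neutral sphingomyelinase. Cells of each genotype were kept without serum for 24 h, or without serum for 8 h and then with tumour necrosis factor (TNF, 50 ng/ml) for 16 h. Total RNA of these 4 conditions was hybridised to Affymetrix whole-genome mouse arrays, 1 array per condition, each giving 45101 probe set values. The design asks how these cells respond to TNF and whether the response differs without FAN. The arrays were grouped by title and source name, which name 4 different conditions. The genotype entry of 2 samples disagrees with this: it calls the TNF-treated wild type a knockout and the untreated knockout a wild type.

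Median log2 values lay between 6.21 for the untreated wild-type array and 6.3 for the TNF-treated knockout array, and between 49.2% and 50.5% of probe sets lay above the floor of 77.0 signal units. The b-actin 3' to 5' ratio was 1.32 to 1.39 and the Gapdh ratio 1.03 to 1.09 on the 4 arrays. The hybridization spikes were less even. Their median signal was 737 on the untreated and 676 on the TNF-treated wild-type array, against 593 and 622 on the knockout arrays. No condition had a replicate, so a difference between 2 arrays has no replicate check and carries no p-value, and the number of arrays limits the precision of every value. For 1 array against 1, "higher" and "lower" therefore describe these arrays. "Rose" and "fell" are kept for genes past an additive limma test, in which each treatment and each genotype has 2 arrays.

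Nsmaf was lower on both knockout arrays. Its probe set gave signals of 496 in untreated and 376 in TNF-treated wild-type cells, against 240 and 179 in knockout cells. The knockout value was 2.07-fold lower without TNF and 2.10-fold lower with TNF, and limma gave a genotype difference of -1.06 ± 0.11 log2 (SE, adjusted p = 0.019). This direction goes with the titles. The signal stayed above the floor in knockout cells, and a probe set outside the deleted part of the gene would check nothing; which part was deleted is not given in the sources used here. Of the 9 FAN-related and BEACH family genes above the floor, Nsmaf alone reached a 2-fold difference between genotypes.

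In wild-type cells TNF was accompanied by far higher transcripts of chemokines, which attract leukocytes, and of genes of the NF-kB pathway. Ccl5 was 179.6-fold higher, going from a signal of 81.8 to 14699. Ccl20 was 51.4-fold, Cxcl2 45.5-fold, Gbp6, an interferon-inducible GTPase, 38.0-fold, Ch25h, which makes 25-hydroxycholesterol, 22.0-fold, and Ccl9 21.6-fold higher. Cxcl10 was at least 38.3-fold, Il6 at least 32.7-fold and Gbp3 at least 10.4-fold higher, since their untreated values lay at the floor. Ccl2 was 9.11-fold, Ccl7 7.20-fold, Tnfaip3, a ubiquitin-editing inhibitor of NF-kB, 13.6-fold, Sod2 5.46-fold, Icam1 4.48-fold and Vcam1 3.17-fold higher. Nfkbia, which encodes an NF-kB inhibitor, was 1.89-fold higher from a high untreated signal of 8787, and Cxcl1 only 1.47-fold higher from 8725. The acute-phase transcript Saa3 was 14.6-fold, Lcn2 3.83-fold and the matrix protease Mmp3 4.08-fold higher. Lower transcripts were led by Map2 (10.5-fold), Omd (7.14-fold), the Wnt antagonist Dkk2 (6.73-fold), Palmd (5.47-fold), Lmcd1 (5.46-fold) and Osr2 (5.44-fold). Nrk was at least 8.17-fold, Ppp1r3c at least 7.82-fold and Lrrn3 at least 6.89-fold lower. In all, 269 genes were at least 2-fold higher and 235 at least 2-fold lower.

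The gene lists fixed in advance moved accordingly on the wild-type arrays. The median log2 difference was 2.50 for 19 chemokine genes above the floor, of which 11 were at least 2-fold higher, and 1.38 for 17 NF-kB pathway genes, of which 11 were. It was 1.94 for 9 complement and acute-phase genes, 1.23 for 11 redox and prostaglandin genes, 1.15 for 14 antigen presentation genes and 1.02 for 26 interferon-stimulated genes. It was 0.91 for 11 cytokine genes and 0.70 for 8 leukocyte adhesion genes. Each of these medians lay above all 10000 random lists matched on expression, which describes these arrays and tests nothing about the condition. The cell cycle list lay on the other side, with a median of -0.61 over 19 genes, all of them negative, below all random lists. Smaller shifts were seen for cell death genes (0.19, percentile 99.99), proteases and their inhibitors (0.11, percentile 99.0), contractile genes (-0.19, percentile 2.31) and Hox genes (-0.25, percentile 0.65). Medians of the matrix, p53 target, sphingolipid, cholesterol synthesis, FAN and BEACH family, housekeeping and Nsmaf neighbour lists lay within the middle 95% of random lists.

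In knockout cells the same kinds of genes were higher with TNF. Saa3 was 46.2-fold, Mmp3 35.8-fold, Cxcl10 28.5-fold, Ccl2 20.5-fold and the NF-kB inhibitor gene Nfkbie 15.1-fold higher. Ccl20 went from a signal of 117 to 2688. Ccl5 was at least 43.1-fold, Cxcl2 at least 23.1-fold, Steap4 at least 6.61-fold and Il6 at least 3.82-fold higher. Tnfaip3 was 14.7-fold, Ccl7 9.20-fold, Cxcl1 7.36-fold, Vcam1 4.86-fold, Icam1 4.40-fold and Sod2 2.41-fold higher. Lower transcripts were led by Egfl6 (8.05-fold), the imprinted gene Mest (6.97-fold), Omd (5.30-fold), Col8a2 (4.58-fold), Elobl (4.51-fold) and Ror1 (4.23-fold), and Palmd was at least 6.41-fold lower. In all, 165 genes were at least 2-fold higher and 131 at least 2-fold lower. The list medians were 2.52 for 16 chemokine genes, 1.32 for 17 NF-kB genes, 0.76 for 9 complement and acute-phase genes, 0.70 for 13 antigen presentation genes, 0.62 for 10 cytokine genes, 0.60 for 11 redox genes and 0.52 for 24 interferon-stimulated genes, all above all random lists. The cell cycle median was -0.03 over 17 genes, at percentile 22.5, and the matrix median was -0.28 over 20 genes, below all random lists. Smaller shifts were seen for cell death genes (0.19, percentile 99.95), p53 targets (-0.18, percentile 1.09), Hox genes (-0.17, percentile 0.11), contractile genes (-0.16, percentile 0.73) and Nsmaf neighbours (-0.20, percentile 0.45).

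**Figure D1:**
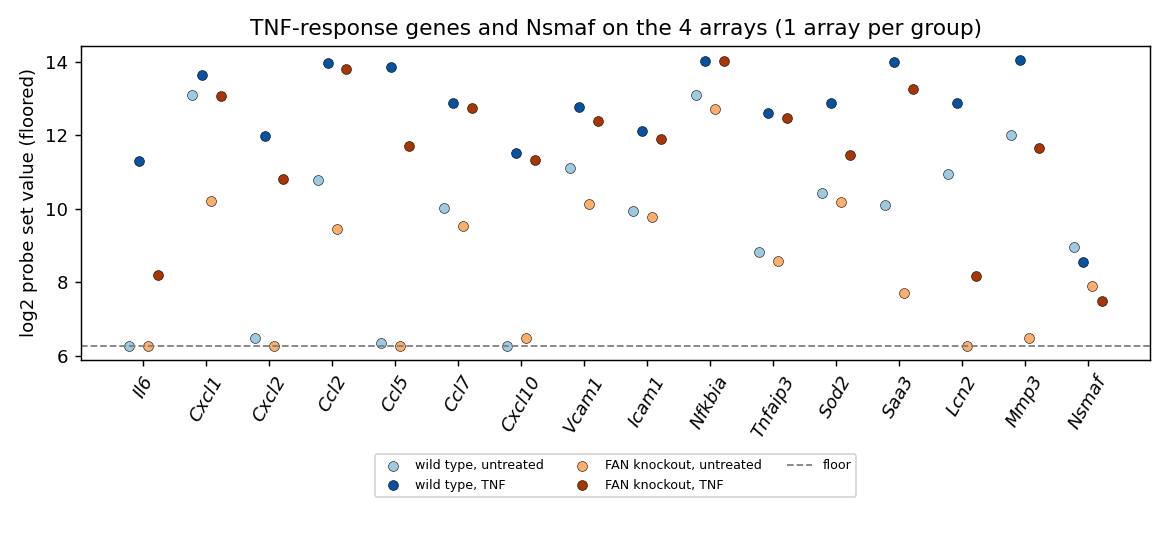
Log2 probe set values of TNF-response genes and Nsmaf (horizontal axis) on the 4 arrays, 1 point per array, with values under the floor raised to it (dashed line). Nsmaf is lower on both knockout arrays, and Il6 with TNF is 11.30 in wild-type and 8.20 in knockout cells.

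The additive fit asked what both genotypes share. With TNF, 186 genes rose and 135 fell out of 11817 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Ccl5 rose by 6.46 ± 0.49 log2 (SE, adjusted p = 0.016), and Ccl20 by 5.10, Cxcl10 by 5.05, Cxcl2 by 5.02, Saa3 by 4.70 and Ch25h by 4.15. Omd fell (-2.62 ± 0.15 log2, adjusted p = 0.011), as did Egfl6 (-2.60), Palmd (-2.57), Ppp1r3c (-2.46), Aspn (-2.17) and the growth factor gene Fgf18 (-2.13). Of 17 NF-kB pathway genes 12 rose, among them Nfkbie (3.88), Tnfaip3 (3.82) and Birc3 (2.53), and 16 rose when adjusted over the list alone. Of 17 chemokine genes 9 rose (12 higher and 1 lower adjusted over the list alone), of 24 interferon-stimulated genes 9 rose (15), of 13 antigen presentation genes 5 rose (11), of 9 complement and acute-phase genes 4 rose (7), and of 11 redox genes 4 rose (7). Other lists had few members past the test: 3 of 11 cytokine genes rose (6 adjusted over the list alone), 3 of 20 cell death genes rose (4), and of 8 adhesion genes Icam1, Vcam1 and Cd44 rose while Alcam and Mcam fell (5 and 2 adjusted over the list alone). Mmp9, Mmp13 and Timp1 rose among 17 proteases and inhibitors (6 higher and 3 lower adjusted over the list alone), and Eln and Postn fell among 20 matrix genes (2). Cnn1 fell among 14 contractile genes (5 lower adjusted over the list alone) and Hoxa10 among 23 Hox genes (4), and no cell cycle, p53, sphingolipid, cholesterol, housekeeping, FAN family or Nsmaf neighbour gene passed. Adjusted over the list alone, 3 of 8 housekeeping genes were higher and 1 p53 target lower, so such counts also take in genes of a list set as a reference. Il6 (adjusted p = 0.10), Cxcl1 (0.21), Mmp3 (0.099), Cfb (0.12) and Sod2 (0.058) did not pass, because the fit takes a response that differs between genotypes as error.

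These counts rest on 1 residual degree of freedom. They were 0 and 0 when all probe sets of a gene were averaged (988 higher and 1119 lower at an unadjusted p under 0.05) and 0 and 0 without the genotype term (450 and 434). With camera at a preset correlation of 0.01 the chemokine, NF-kB, interferon, antigen presentation, complement, cytokine, redox, cell death and adhesion lists passed upward, and the matrix, contractile, Hox, cartilage and fibroblast lists downward; none of them did with an estimated correlation (adjusted p = 0.53). The cell cycle list passed downward at the preset correlation (adjusted p = 0.0012) and not with an estimated correlation (adjusted p = 0.61). With an estimated correlation, camera has only the 1 residual degree of freedom of the fit, so hardly any list could pass. For the NF-kB pathway the estimate was -0.059, below the preset 0.01, and camera still gave an unadjusted p = 0.064. The failures with an estimated correlation therefore decide little about any list. Other estimates lay on both sides of the preset. They were 1 for cell cycle, 0.56 for complement and acute-phase and 0.22 for interferon-stimulated genes. For these lists the p-values at the preset assume far less correlation than was estimated, so their passes decide little either. With fry for a common direction no list passed for TNF, the NF-kB pathway coming closest (adjusted p = 0.051). With fry for changes in either direction the cytokine and adipocyte lists (0.0095), the NF-kB and adhesion lists (0.045) and the contractile list (0.047) passed.

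The response was then compared between genotypes. Across 12225 genes the log2 responses correlated at r = 0.70, a correlation across genes, which are not independent replicates. Of the genes at least 2-fold higher, 123 were so in both genotypes, where independent lists would share 3.63, and 69 were lower in both, where 2.52 would be shared; no gene was 2-fold higher in one and 2-fold lower in the other. For the 187 genes whose mean response over both genotypes was at least 2-fold higher, the median response was 1.69 log2 in wild-type and 1.36 in knockout cells. The median gene-by-gene difference was -0.30 (95% bootstrap interval over genes -0.40 to -0.22), and 128 of them had the smaller response in knockout cells. For 139 genes lower with TNF the medians were -1.45 and -1.18, with a difference of 0.25 (0.12 to 0.39). This gap depended on how responders were chosen. It was -0.57 for genes 2-fold higher in wild-type cells and 0.05 for genes 2-fold higher in knockout cells. For lower genes it was 0.68 when chosen in wild-type cells and -0.28 when chosen in knockout cells, where only 45 of 131 had the smaller response in knockout cells, so the direction turned with the choice. Choosing by 1 genotype favours genes whose response happens to be large there. The turn is thus partly built in and cannot decide the direction. The bootstrap intervals cover the choice of genes and not the variation between cultures.

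**Figure D2:**
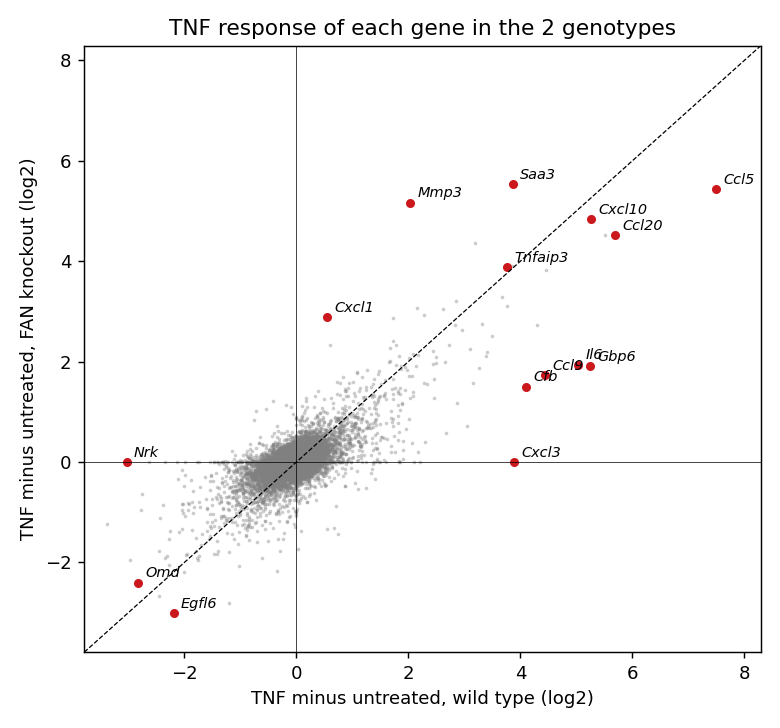
TNF response of each gene (log2, TNF minus untreated, values floored) in wild-type cells (horizontal axis) and in knockout cells (vertical axis), 1 point per gene and the dashed line marking equal responses. Mmp3 lies at 2.03 and 5.16, Ccl5 at 7.49 and at least 5.43, and Il6 at no less than 5.03 and 1.93, as the untreated values of Ccl5 in knockout cells and of Il6 in both genotypes were at the floor.

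Individual genes departed from the shared response in both directions. Il6 lay at the floor untreated in both genotypes and reached a signal of 2520 with TNF in wild-type cells and 294 in knockout cells. Gbp6 went from 114 to 4326 in wild-type cells and from the floor to 288 in knockout cells, and Cxcl3 from 152 to 2252 in wild-type cells while staying at the floor in knockout cells. Cfb, a complement factor, responded 17.1-fold in wild-type and 2.83-fold in knockout cells. Mmp3, Cxcl1 and Saa3 had larger fold responses in knockout cells, from lower untreated signals: 89.0 against 4135 for Mmp3, 1173 against 8725 for Cxcl1 and 210 against 1105 for Saa3. With TNF their knockout signals (3186, 8636 and 9717) were still below the wild-type ones (16852, 12793 and 16155). These wild-type values (log2 14.04, 13.64 and 13.98) lay close to the maximum of that array (14.36), and the untreated knockout value of Mmp3 lay close to the floor. Whether either limit shaped the folds was not tested. Dkk2, Plin4 and Msx1 were lower with TNF mainly in wild-type cells, and Ptgfr and Prr16 were higher mainly there. In all, 97 genes had a response at least 2-fold larger or less negative in knockout cells and 100 the reverse. Centring the arrays changed this split to 72 and 122. Before centring, 39 of the 97 genes and 40 of the 100 had a value at the floor among the arrays compared. The size of their differences was therefore not fully measured.

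By list, the difference of responses had a median of 0.06 for the NF-kB pathway (17 genes, percentile 50.6 of random lists) and -0.41 for interferon-stimulated genes (26 genes, 6 of them positive, below all random lists). Among the latter Iigp1 had signals of 603 with TNF in wild-type and 115 in knockout cells, and Ifi47 responded 9.60-fold and 3.65-fold. Over the 16 members above the floor on all 4 arrays the median was -0.14 (95% bootstrap interval -0.50 to 0.08), which includes both 0 and -0.41; low knockout values themselves decide which members this keeps. The median was -0.33 for chemokines, -0.30 for antigen presentation, -0.37 for cytokines, -0.29 for complement and acute-phase genes, -0.18 for proteases, -0.16 for cholesterol synthesis and -0.15 for matrix genes, each at percentile 0.10 or lower. Over members above the floor on all 4 arrays, the chemokine median was 0.01 (95% bootstrap interval -0.52 to 1.21, 10 genes). It was -0.24 (-0.48 to 0.06) for antigen presentation and -0.53 (-1.57 to 0.30) for cytokines. These intervals include 0, and that of complement and acute-phase genes does not (-0.29, -0.68 to -0.23, 7 genes). The negative chemokine median was thus not seen among these 10 genes, although their interval includes -0.33 too. Without that restriction the cell cycle median was 0.47, all 19 genes positive. The leukocyte marker median was -0.65 over 6 genes, below all random lists, with Lyz2 at -1.87 and Csf1r at -1.27. Unlike the interferon list, these markers were higher in untreated knockout cells (median 0.40, percentile 99.5) and level with TNF (0.01). The adhesion, redox, contractile, cell death, p53, sphingolipid, FAN family, housekeeping, Nsmaf neighbour and Hox lists lay within the middle 95% of random lists. None of these differences was tested, since no degree of freedom is left for the interaction.

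The genotypes differed in many genes in both treatments. Untreated knockout cells had 177 genes at least 2-fold higher and 353 at least 2-fold lower than untreated wild-type cells, and with TNF the counts were 189 and 323. Of these, 105 were higher and 179 lower in both treatments, and the differences correlated at r = 0.74 across genes. Penk, the enkephalin precursor gene, was 131.3-fold lower untreated and 71.1-fold lower with TNF, and the Wnt modulator Sfrp2 was 68.6-fold and 69.8-fold lower. Mmp3 (46.5-fold), Cxcl15 (40.2-fold), Hoxd13 (17.8-fold) and Coch (15.9-fold) were also lower in untreated knockout cells, and Lcn2 at least 25.4-fold, Reln at least 11.7-fold and Steap4 at least 11.1-fold. With TNF the keratan sulfate proteoglycan Lum was 62.7-fold, Lcn2 26.2-fold, Mest 22.0-fold and Coch 19.1-fold lower. Higher in knockout cells were Plac8 (7.33-fold untreated, 7.07-fold with TNF), the junction protein gene F11r (6.89 and 6.16-fold), C1qtnf3 (5.43 and 7.77-fold), and, untreated, Elobl (6.54-fold), Ctla2a (5.07-fold) and Spns2 (5.05-fold). With TNF, Itga8 was 5.98-fold, Col7a1 5.90-fold and Cck 5.70-fold higher. Cd99 lay at the floor in wild-type cells and was at least 17.3-fold and 25.2-fold higher in knockout cells.

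**Figure D3:**
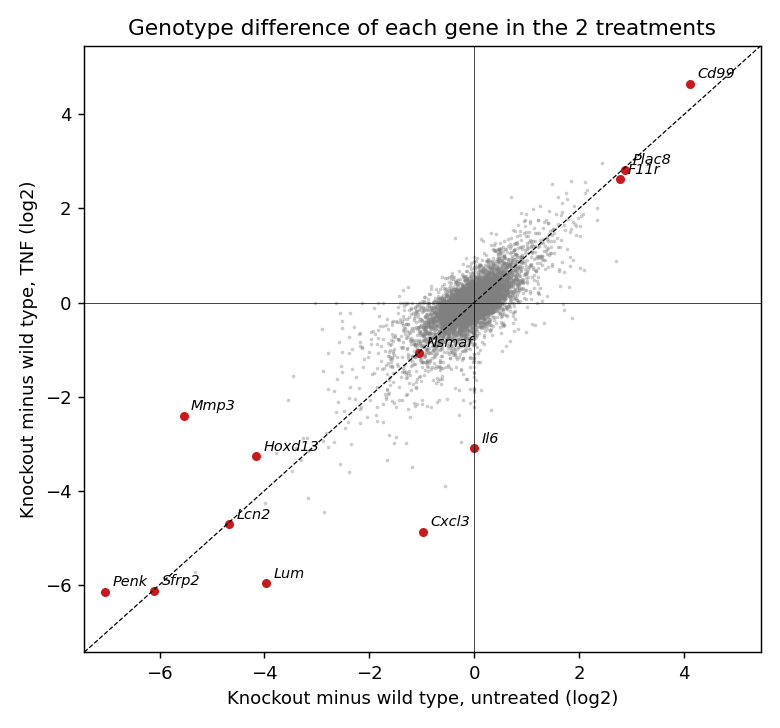
Knockout minus wild-type difference of each gene (log2, values floored) without TNF (horizontal axis) and with TNF (vertical axis), 1 point per gene and the dashed line marking equal differences. Penk and Sfrp2 lie beyond -6 in both, Nsmaf at -1.05 and -1.07, and Cd99 at no less than 4.12 and 4.66, being at the floor in wild-type cells.

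In the additive fit 347 genes were higher and 435 lower in knockout cells (limma, adjusted p under 0.05), and 92 and 106 when all probe sets of a gene were averaged. Penk fell by 6.59 ± 0.23 log2 (SE, adjusted p = 0.0031), Sfrp2 by 6.11, Cxcl15 by 5.53, Lum by 4.97, Lcn2 by 4.69 and Coch by 4.12, while Cd99 rose by 4.39, Plac8 by 2.85, F11r and C1qtnf3 by 2.70, Col7a1 by 2.34 and Serpinb6b by 2.26. Of 18 cell cycle genes 8 fell (13 adjusted over the list alone), led by Mki67 (-2.00), Top2a (-1.74) and Mcm5 (-1.63). The list as a whole passed camera at the preset correlation (adjusted p = 1.9e-07). It passed neither fry (adjusted p = 0.28) nor camera with an estimated correlation (adjusted p = 0.59). Of 11 genes of the p53 target list 5 rose (10 adjusted over the list alone), namely Pmaip1 (1.56), Mdm2 (1.18), Trp53inp1 (0.78), Cdkn1a (0.64) and Ccng1 (0.63). Of 23 Hox genes 11 rose and 2 fell (12 and 7 adjusted over the list alone): Hoxc6 (1.68), Hoxc8 (1.66) and Hoxc10 (1.53) rose, and Hoxd13 (-3.71) and Hoxa11 (-1.64) fell. Of 24 interferon-stimulated genes 5 fell, among them Ifit1 (-1.68) and Ifih1 (-1.32), and Irgm1 rose (0.72); the list alone gave 11 and 1. Of 13 antigen presentation genes 5 fell (8 lower and 1 higher for the list alone), of 9 complement and acute-phase genes 4 fell (8) and of 16 cholesterol synthesis genes 4 fell (14), Idi1 among them (-0.87). Among 20 matrix genes Lum, Col6a1, Col6a2, Col6a3 and Dcn fell and the basement membrane genes Col4a1 and Col4a2 rose. No NF-kB pathway gene out of 17 passed. Few members of other lists did: Cx3cl1 (-1.37) among chemokines, Sgms2 (-0.65) among sphingolipid enzymes, Mmp13 (-2.99) and Ctsk (1.03) among proteases, Tslp (-3.24) and Il11 (1.22) among cytokines, and F11r (2.70) and Mcam (1.10) among adhesion genes. Of 11 redox genes 2 rose and 2 fell, and of 20 cell death genes 1 rose and 2 fell.

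By list, the complement and acute-phase median was -1.05 untreated and -1.57 with TNF, the cell cycle median -1.01 and -0.57, the antigen presentation median -0.60 and -0.70, the cholesterol median -0.49 and -0.67 and the interferon median -0.38 and -0.72, each at percentile 0.01 or lower. The medians of the p53 target list were 0.70 and 0.54 and the Hox medians 0.39 and 0.29, all above all random lists. Of the 4 members of the p53 target list at least 2-fold higher untreated, Cdkn2b (1.22) and Cdkn2a (1.06) are not p53 targets. The Nsmaf neighbour medians were -0.05 and -0.07, inside the middle 95% of random lists. In limma, however, 2 of 11 fell, Tox (-1.74) and Fam110b (-0.96), and 3 when adjusted over the list alone. The list had an adjusted p of 0.036 with fry and of 0.18 with camera at the preset correlation.

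With camera at the preset correlation the cell cycle, p53, Hox, interferon, antigen presentation, complement, cholesterol, contractile, neural and muscle lists passed. With an estimated correlation none did (adjusted p = 0.59 for cell cycle and 0.57 for the others). That version of camera again had only 1 residual degree of freedom, so its failure decides little. Passes at the preset of 0.01 decide little for lists with far higher estimates. These include cell cycle (1), complement (0.56), cholesterol (0.31) and interferon (0.22), while the p53 (-0.018) and Hox (-0.028) estimates lay below it. With fry for a common direction the Hox and Nsmaf neighbour lists (adjusted p = 0.036) and the adhesion and redox lists (0.040) passed, and the cell cycle list (0.28), p53 targets (0.064) and the interferon list (0.24) did not; for either direction only the FAN family list, which holds Nsmaf, passed (0.046). Each genotype has 2 arrays that may share a single cell preparation, so these values compare these cells and not necessarily the genotypes.

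Lists of other cell types were read beside these. Neural markers Stmn2, Nes and Tubb3 rose in knockout cells (1.35, 1.06 and 1.24), while the cartilage markers Comp (-3.49) and Col2a1 (-1.47), the adipocyte marker Fabp4 (-2.21) and the fibroblast markers Pdgfra (-1.62), Twist1 (-1.04) and S100a4 (-0.54) fell. The neural list median was 0.37 untreated, but its mean was -0.0539, with Map2 among 2 of 7 members at least 2-fold lower. With TNF in wild-type cells the cartilage median was -0.53, the adipocyte median -0.56 and the leukocyte marker median 0.40. In knockout cells they were -0.39, -0.27 and -0.17, and the fibroblast marker median was -0.27 (percentile 0.06) against -0.15 in wild-type cells. Des rose among 5 muscle markers, no member of the leukocyte, endothelial or epithelial lists passed, and no erythroid marker lay above the floor. Sphingolipid enzymes differed little: of 24 genes above the floor, none was 2-fold apart between untreated genotypes (median -0.20), and with TNF only Ugcg was (2.56-fold lower in knockout cells). Their TNF response had a median of 0.01 in wild-type and -0.01 in knockout cells, with Ugcg 2.69-fold higher in wild-type cells. The housekeeping list had genotype medians of -0.04 in both treatments.

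**Figure D4:**
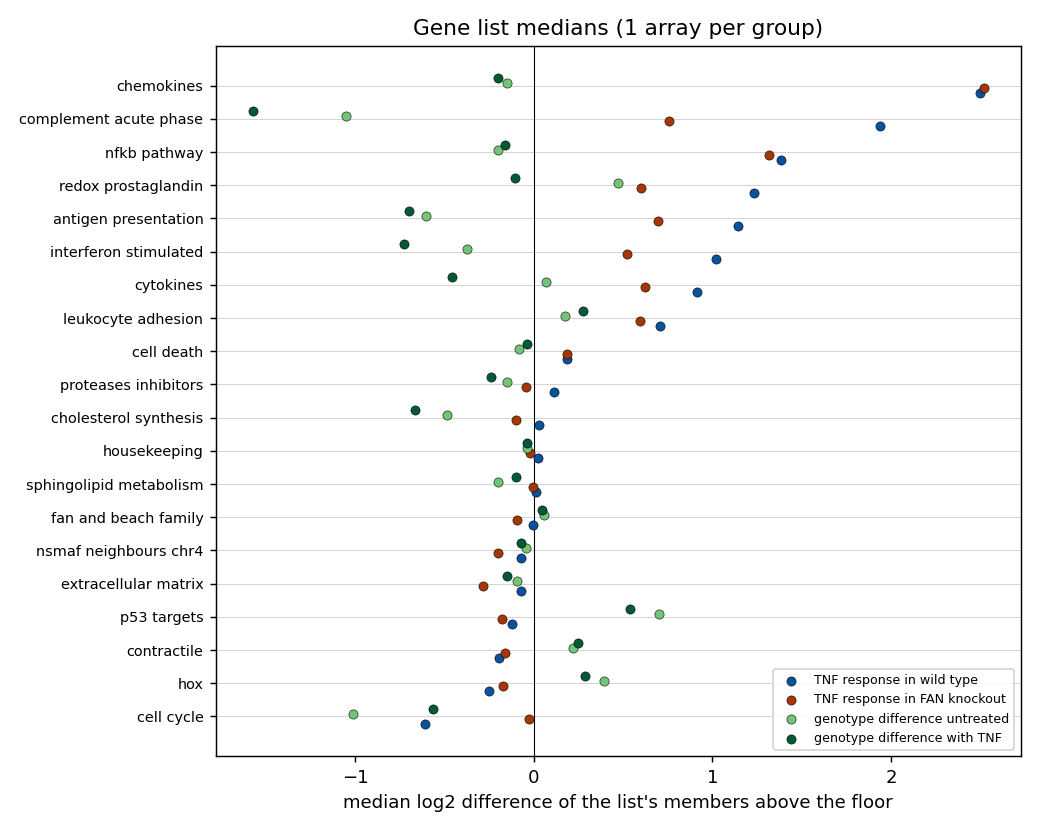
Median log2 difference (horizontal axis) of the members above the floor of each gene list fixed in advance (vertical axis), for the TNF response in each genotype and the knockout minus wild-type difference in each treatment. Chemokine medians are 2.50 and 2.52 for TNF, and the cell cycle medians are -1.01 and -0.57 between genotypes.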

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

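The tests of positional identity, sex, response slope, floor, a single deviating array and dividing cells were all written after the list medians had been seen, as was the 0.5 log2 minimum for an opposite response. The test of a donor segment around Nsmaf as the whole cause was written before its result, although the values of Penk and Tox were already known.

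A few named genes moved in opposite directions with TNF in the 2 genotypes; these differences were not tested, as each rests on 4 single arrays. The knockout response minus the wild-type response was 1.74 log2 for Ano1 (-0.72 in wild-type, 1.02 in knockout cells), -2.18 for Lyz1 (0.75 and -1.43), -1.87 for Lyz2 (0.55 and -1.33) and -2.00 for Lum (0.68 and -1.32). Lyz1 and Lyz2 are near-identical paralogs and count as 1 observation. Among 10092 probe sets with no single gene name, which the comparisons leave out, 25 were at least 2-fold higher with TNF in both genotypes and 6 at least 2-fold lower.

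The widest pattern is the set of genes that differ between knockout and wild-type cells in both treatments. A segment of donor chromosome around the targeted gene that alters only genes near it is argued against as the whole cause. Only 2.05% of the called genes lie among the 200 tested genes nearest to Nsmaf, and 763 called genes lie elsewhere. A window of 200 genes could not have held most of these calls, so the outcome set for this cause was out of reach. Only the number of calls elsewhere argues against it. The share of genes called was 8.0% in the window and 6.6% elsewhere. None of these values can speak to an effect of such a segment on genes elsewhere, which was not tested. A difference in sex is argued against as well: 0 of 9 Y-linked probe sets of 3 genes lay above the floor on any array, and Xist was between 12.04 and 12.38 on all of them. Cells of another positional identity, such as other parts of the embryo, stay open: Hox genes were called more often than other genes (odds ratio 18.6, 95% interval 7.52 to 47.6, two-sided Fisher exact test), but this explanation was drawn from the same Hox values. The interval also takes the Hox genes as independent of each other and does not cover the variation between cultures. The preparation of the cells is confounded with genotype, and an effect of FAN itself was not tested apart from it.

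Interferon-stimulated genes responded less to TNF on the knockout arrays. The slope of knockout on wild-type responses was 0.97 (95% bootstrap interval 0.86 to 1.06, 16 genes) for the NF-kB pathway and 0.76 (0.63 to 0.90, 16 genes) for the interferon list, a difference of 0.22 (0.04 to 0.38). The interval of the difference lies above 0. That of the NF-kB slope leaves out 0.76, as does that of the chemokine slope (0.85 to 1.38, 10 genes). Over genes above the floor on all arrays, the slopes thus differed between these lists. This cannot count against an equally weaker response of every TNF-induced gene as the whole cause, because the rule was set with values in view. A weaker response shared by some lists stays open, since the intervals of the antigen presentation (0.81, 0.66 to 0.94), cytokine (0.65, 0.45 to 1.32) and complement slopes (0.84, 0.37 to 1.36) include 0.76; values at the floor stay open too, since the median difference over members above it on all arrays was -0.14 (-0.50 to 0.08). These intervals cover the choice of genes alone, and this rule replaced one on the separate intervals, which overlap, after the values were seen.

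Of 18 cell cycle genes 8 fell in knockout cells. The list as a whole passed camera at the preset correlation (adjusted p = 1.9e-07). It passed neither fry (adjusted p = 0.28) nor camera with an estimated correlation (adjusted p = 0.59). The latter rests on 1 residual degree of freedom and could hardly pass. The estimated correlation was 1 against the preset 0.01, so the small p-value at the preset rests on near independence of these genes. A single deviating array, the untreated wild type, as the whole cause stays open: the median was -0.57 between the TNF arrays, which leave that array out, but these are 1 array against 1, and random lists give no spread for genes that move together. Fewer dividing cells in the knockout culture stay open as a candidate explanation: the p53 target median was 0.54 on the same arrays, but this was known when the test was written, so it could not have come out otherwise. No count of dividing cells was used here.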

How the results depend on the processing

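All alternatives below were set before any value was seen; only the gene windows around Nsmaf were added later. No paired analysis was possible because each condition has 1 array and no replicate number pairs the arrays; the additive model itself compares TNF within each genotype. No array could be left out, since that leaves the additive model no residual degree of freedom. With thresholds of 1.5-fold and 3-fold in place of 2-fold, the genes higher and lower numbered 581 and 794, and 110 and 61, for TNF in wild-type cells; 390 and 379, and 67 and 28, in knockout cells; 444 and 346, and 21 and 30, for the difference of responses; 540 and 903, and 52 and 133, between untreated genotypes; and 547 and 733, and 48 and 124, with TNF, as the thresholds' construction implies. With a floor at the 70th percentile, 154 genes were lower with TNF in wild-type cells, 103 higher and 219 lower between untreated genotypes and 112 higher with TNF, and Nsmaf differed by -0.71 log2 with TNF, where fewer genes and smaller differences lie above the floor. Other floors, normalizations and probe set rules kept the 2-fold counts within 1.5 times. The limma TNF counts were 0 and 0 with the mean of all probe sets and 0 and 0 without the genotype term. They were 115 and 71 without a floor, and the genes lower were 234 with the higher floor and 213 for genes above the floor on all arrays. The genotype counts were 92 and 106 with the mean of all probe sets. Apart from the missing genotype term, which leaves the genotype difference in the error, the cause was not tested. The knockout minus wild-type response of genes higher with TNF had a median of -0.35 after centring and -0.37 with the mean of all probe sets, and of genes lower with TNF 0.16 after centring; the directions held and the cause was not tested. Of 586 alternative values for the 74 list medians outside the middle 95% of random lists, 399 stayed within the spread, 186 moved beyond it and 1 changed sign: the neural marker difference between untreated genotypes was -0.0539 by the mean. Of 888 values for 127 named genes, 674 stayed, 214 moved and 0 reversed. The median over all genes stayed between -0.04 and 0.05 log2 in every comparison and setting. Signals near the floor limit what can be said of weakly expressed genes such as Il6 before treatment.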

Other observations

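The genes named here were chosen from the fixed lists after their values were seen, and stand for no common theme. The metallothionein gene Mt2 rose with TNF by 2.60 log2 and Gch1, which makes a cofactor of nitric oxide synthase, by 2.32, in the limma fit. In knockout cells Nqo1, an NRF2 target, rose by 1.56 and Txnrd1 by 0.72, while Gch1 fell by 1.40. The cytokine gene Tslp fell by 3.24 and the caspase gene Casp4 by 1.65 in knockout cells, and both rose with TNF, by 1.61 and 2.61. The smooth muscle actin gene Actg2 rose by 1.79 in knockout cells, and Cnn1 fell with TNF by 1.03. Between genotypes the redox list as a whole passed fry (adjusted p = 0.040) and not camera at the preset correlation (adjusted p = 0.77).

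A hypothesis is that DNA of the donor strain around Nsmaf may alter some neighbouring genes. The test set in advance, with Penk and Tox already seen, compared the 200 tested genes nearest to Nsmaf with the rest: 16 were called, an odds ratio of 1.23 (95% interval 0.69 to 2.07, two-sided Fisher exact p = 0.39), which decides nothing. The nearest 20, 50 and 100 genes were also tried, with odds ratios of 3.54, 1.93 and 1.06. The nearest 30 were tried last, with the called neighbours already in view, and gave 3.54 (1.18 to 8.93, exact p = 0.012 before and 0.062 after adjustment for the 5 windows). A window picked in sight of the genes that show the pattern cannot bear the hypothesis out, and the adjustment does not undo that choice. The mean absolute difference of those 30 genes lay at percentile 99.6 of 11183 windows of this size, and at 92.6 without Penk. In addition, 8 genes on unlocalized scaffolds, Cd99 among them, were left out of this test after Cd99 had been noticed there. The neighbour list fixed in advance passed fry (adjusted p = 0.036) and not camera at the preset correlation (adjusted p = 0.18). The question stays open.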
